A study of Mus musculus with 32 samples.

How the data were processed

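Gene expression was measured by RNA sequencing in cochleae of 10-week-old mice, without noise or 6 h or 24 h after 2 h of noise at 105 dB SPL. The mice carried RiboTag, an allele that adds an HA tag to the ribosomal protein Rpl22 in cells that express Cre, so that ribosomes of those cells can be pulled down with an antibody. Cre was driven by Prestin (Slc26a5, outer hair cells) in 1 strain and by Sox2 (supporting cells) in the other. Per the labels' protocols, each homogenate gave an aliquot of total RNA (input, the whole cochlea) and an HA immunoprecipitate (IP), and libraries were made with the NEBNext Ultra Directional kit from biological triplicates. The series holds 32 libraries in 12 groups. All Prestin groups hold 3 libraries, the Sox2 groups hold 2 libraries each without noise and at 6 h and 3 each at 24 h.

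The deposited files give TPM, each gene's length-scaled share of a library's reads, per gene and library, and each library sums to 1000000. TopHat and the GRCm38 build are named in the submitters' processing notes. The tool that counted reads, the tool that made the TPM values, the annotation, the version of each and the use of strand are not given in the sources used here. TPM values keep no read depth, so the depth behind each value is unknown and no counting interval was given. The Prestin files list 39399 genes and the Sox2 files 43947, of which 4548 are listed there alone and hold 2.19% to 2.85% of the TPM of a Sox2 library. Comparisons across the strains used the 39399 shared genes. Gene symbols are those of the files. GENCODE M21, used for positions, length, GC content and gene type, held 99.86% of the Prestin identifiers and 99.88% of the Sox2 identifiers.

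Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. All log2 fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. They are given as log2 fold change ± standard error of the fit, and levels as mean TPM ± SD over the libraries of a group. A gene was tested where it reached 1 TPM in at least as many libraries as the smallest group of the fit holds (3 for Prestin, 2 for Sox2, 5 for the inputs of both strains). IP was compared with input within a strain as the mean over the 3 conditions. Each IP response to noise was fitted on the IP libraries of its strain, and the input response on all inputs with the strain as a covariate. Differences of responses were tested as interaction terms. The difference between the strains' enrichments was added after the data were seen, over all 32 libraries. Gene lists were tested against all other genes with camera (limma), with a preset correlation of 0.01 between genes and again with an estimated correlation. There were 14 cell type lists and 17 response lists, each with at least 4 measured members. Counts of list members are over the members tested in that comparison, which can be fewer than the list holds. Figures were drawn with matplotlib 3.10.9, and files were read with pandas 2.3.3 in python 3.11.15 and numpy 2.4.6.

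Groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, up to 8 genes with the largest rise and 8 with the largest fall among those past the threshold, with a mean of at least 5 TPM in the higher group and no overlap between the libraries of both groups. For IP against input, every IP had to lie on the same side of its own input; for interactions the overlap was not asked. Predicted genes, numbered pseudogenes and genes of microRNAs, small nucleolar, small nuclear and other small RNAs with such symbols were left out, but not mitochondrial tRNAs. It added up to 4 members with the smallest p of each list described, and Slc26a5, Sox2 and Rpl22 in both enrichments. Where no gene passed, the rule took the 5 with the smallest p, of any type. That part took the microRNA gene Mir3074-1, the only gene called in its comparison. Of the secondary comparisons and interactions, the text names some of the genes the rule takes. A few other genes the rule takes are not reported here.

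IP and input of the same homogenate pair by design. Their deviations from the group means correlated across genes with r from 0.019 to 0.267 in the 16 homogenates, and in all 16 the IP correlated more with its own input than with any other input of its group. In the Sox2 groups of 2 libraries the deviations are mirror images, so both homogenates of such a group give the same check. Fits with the homogenate as a block were run as alternatives, and their values stand beside a result where they move its count by over 1.5 times. Other alternatives were a pseudocount of 0.1, no filter, median-of-ratios scaling between libraries, the replicate number as a block, a joint fit of IP and input libraries, the control libraries alone for enrichment, and leaving out each library or homogenate in turn. Where this left a group with 1 library, that library was assumed to vary like the other groups. Alternatives added after seeing the data were rescaling without mitochondrially encoded genes, Malat1 and Mir6236, a mean of at least 5 TPM, removal of each library's trend on GC content, the hair cell lists without the Prestin control IP replicate 1, and the medians of the hair bundle genes in the outer hair cell IP without each library in turn.

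Of the 24 comparisons, 15 were tested on simulated data drawn from the real genes' means and spreads. Each had 3 sets, with 200 changed genes per size. The simulated noise was normal and independent between genes and between IP and input, so the rates hold for data that meet the model. Of genes changed by 1 on the log2 scale, 80.5% were recovered in the inputs at 6 h, 23.5% in the outer hair cell IP at 6 h and 0.333% in the supporting cell IP at 6 h. Of genes changed by 2, the shares were 94%, 69.7% and 24.5% in the same comparisons, and 77.2% and 36.2% in the outer hair cell and supporting cell IPs at 24 h. Reads shared between near-identical copies, pseudogenes or overlapping genes could be assigned either way, so genes with such copies are uncertain.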

Results

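The data comprised 32 RNA sequencing libraries from mouse cochlea, made to follow the response of outer hair cells, supporting cells and the whole cochlea to damaging noise. Libraries came from the Prestin strain (HA pull-down of outer hair cell ribosomes) and the Sox2 strain (pull-down of supporting cell ribosomes), each with the matching whole-cochlea input, from mice without noise and 6 h or 24 h after it. Every Prestin group held 3 libraries. The Sox2 IP and input groups held 2 libraries each without noise, 2 at 6 h and 3 at 24 h. Values were TPM, so sequencing depth is unknown. The number of genes listed above 0 ran from 15929 to 21239. The 4 Sox2 libraries at 6 h lay between 15929 and 16966, below the 17395 to 21239 of the other Sox2 libraries. Mitochondrially encoded genes held 20.5% to 28.6% of the TPM of the inputs, 4.91% to 13.7% of the outer hair cell IPs and 3.07% to 8.83% of the supporting cell IPs. Replicates of a group correlated across genes with r from 0.824 to 0.939 in Prestin IPs, 0.950 to 0.972 in Prestin inputs, 0.854 to 0.899 in Sox2 IPs and 0.901 to 0.958 in Sox2 inputs.

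**Figure D1:**
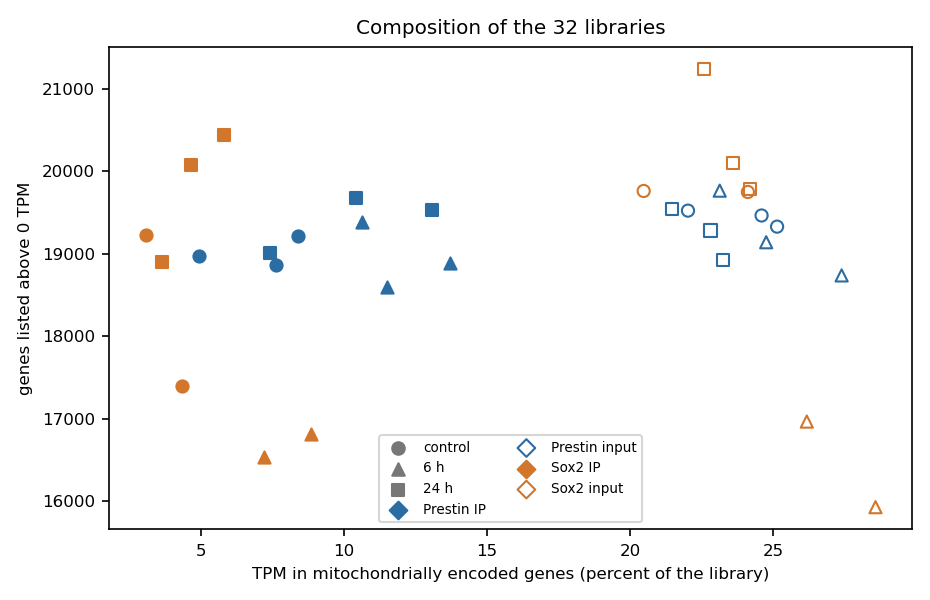
Composition of the 32 libraries. Each point is a library, with the percent of its TPM in mitochondrially encoded genes on the x axis and the number of genes listed above 0 TPM on the y axis; colour gives the strain, fill gives IP or input and shape gives the time. The inputs lie at 20.5% to 28.6% and all IPs at 13.7% or less, and the 4 Sox2 libraries at 6 h list 15929 to 16966 genes.

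The comparison of IP with input asks which transcripts each pull-down enriches. In the Prestin strain, Slc26a5, the motor protein of outer hair cells and the driver of Cre, was higher in the IP by 2.46 ± 0.23 on the log2 scale (adjusted p = 1.61e-07). In control mice it stood at 15.6 ± 9.17 TPM in the IP and 0.998 ± 0.0692 TPM in the input (n = 3 each). Its gene (ENSMUSG00000029015) lies on chromosome 5 of GRCm38, from 21810655 to 21865604. All 11 outer hair cell markers were higher, with a median of 2.30, which is 1.49 above the median of all genes tested. Ocm, a calcium-binding protein of outer hair cells, rose by 3.42 ± 0.17, from 54.8 ± 7.65 to 1141 ± 617 TPM in control mice. Strc rose by 3.27 ± 0.19, Ikzf2 by 2.09 ± 0.11 and Lbh by 1.67 ± 0.08. All 20 hair cell and hair bundle genes were higher, with a median of 1.66, among them the transduction genes Lhfpl5 (2.62) and Tomt (2.57) and the bundle genes Espn (2.22) and Myo15 (1.69). Of 5 inner hair cell markers, 4 were higher, including Tbx2 (2.15) and Otof (0.75), but the list did not differ from other genes (median 0.75, adjusted p = 0.664).

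Among genes of other cells, 15 of 22 supporting cell markers were higher and 2 lower (median 0.59, adjusted p = 0.711), with Lfng at 3.03 and Fgfr3 at 1.82. Of 19 Schwann markers, 15 were higher and 1 lower (median 0.82, adjusted p = 0.401), and of 12 endothelial markers 11 and 1 (median 1.11, adjusted p = 0.139). Macrophage markers had a median of -0.27, which is 1.09 below the median gene, and Mpeg1 (-0.82) and C1qa (-0.54) were lower in the IP. Stria vascularis markers had a median of -0.01, and the melanocyte genes Dct (-1.40) and Mlana (-1.45) were lower. Of 22 oxidative phosphorylation genes, 17 were lower, Ndufa1 by -1.82 and Cox7b by -1.40. The mitochondrial transcripts mt-Co1 (-2.88), mt-Rnr2 (-2.36) and mt-Tw (-4.51) were also lower. The named genes with the largest rises were not hair cell markers: Tnrc6a, which acts in silencing by microRNAs, rose by 5.24, Plagl2 by 5.17, Hic2 by 5.03, Zcchc3 by 4.96 and Tet3 by 4.75. The nuclear RNA Malat1 stood at 12251 to 73023 TPM in these IPs and at 2304 to 4226 TPM in the inputs. A rise in the IP therefore does not by itself mark RNA on the ribosomes of tagged cells. Stria and macrophage markers lay near their input level (medians -0.01 and -0.27), so RNA of other cells was present too. Responses of this IP can therefore not be assigned to outer hair cells alone. Sox2 was higher by 0.53 ± 0.12 and Rpl22, the tagged gene, lower by 0.27 ± 0.07 (log2 -0.27, adjusted p = 0.00186). Adjusted over the list alone, the counts of the outer hair cell, hair bundle, supporting cell, Schwann and endothelial lists stayed the same.

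Over all genes, 13218 of 17363 passed, 11885 higher and 1333 lower. The median gene was higher by 0.82, and with median-of-ratios scaling, which moves it to 0.05, 5649 genes were higher and 5456 lower. With that scaling Sox2 (-0.54) and Otof (-0.05) turned negative. In camera, the outer hair cell markers (adjusted p = 0.00375), hair bundle genes (0.00563), stria markers (0.000422), macrophage markers (0.00051) and oxidative phosphorylation genes (3.49e-21) differed from other genes. None kept this with an estimated correlation, where the adjusted p were 0.428, 0.441, 0.321, 0.309 and 0.0582.

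In the Sox2 strain, Sox2 itself, a transcription factor of supporting cells, was higher in the IP by 3.19 ± 0.20 (adjusted p = 6.24e-07). In control mice it stood at 487 ± 236 TPM in the IP and 48.1 ± 22.0 TPM in the input (n = 2 each). Of 22 supporting cell markers, 20 were higher, and 22 when adjusted over the list alone. Their median was 1.73, which is 1.08 above the median gene. Fgfr3 rose by 2.99, Slitrk6 by 2.86, Otog, a protein of the tectorial membrane, by 2.69, and Cdkn1b, a cell cycle inhibitor, by 1.57. Schwann and satellite glia markers were enriched as well: 18 of 19 were higher and 1 lower, with the same counts adjusted over the list alone and a median of 2.28. Among them were the neural crest factor Foxd3 (3.57), the myelin gene Cnp (2.80), Fa2h (2.71) and the neuregulin receptor Erbb3 (1.91). The Schwann median of 2.28 lies above the 1.73 of the supporting cell markers. Responses of the supporting cell IP can therefore not be assigned to supporting cells alone. Slc26a5 did not pass (-0.17 ± 0.25, adjusted p = 0.591). Of 10 outer hair cell markers, 6 were higher (median 0.82, adjusted p = 0.397), among them Ikzf2 (1.42). Of 15 stria markers, 10 were lower and 2 higher (median -0.38), with Slc45a2 at -1.84 and Dct at -1.57. The macrophage genes Mpeg1 (-1.14), C1qb (-0.86) and Csf1r (-0.57) were lower. As in the outer hair cell IP, Hic2 (4.58), Tnrc6a (4.49), Plagl2 (4.32) and Zcchc3 (4.20) were among the most enriched of the named genes, and mt-Co1 (-3.42) and mt-Rnr2 (-3.31) among the most depleted. Malat1 stood at 8533 to 18789 TPM in the supporting cell IPs and at 2577 to 3870 TPM in their inputs.

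In this strain, 10746 of 18560 genes passed, 10241 higher and 505 lower. The median gene was higher by 0.65, and with median-of-ratios scaling 3440 genes were higher and 3460 lower. Rpl22 was higher by 0.18 ± 0.06, but lower with that scaling (-0.72), in the control libraries alone (-0.17) and after rescaling without mitochondrial genes, Malat1 and Mir6236 (-0.12). The supporting cell markers (adjusted p = 1.2e-05) and Schwann markers (0.000508) differed from other genes, with adjusted p = 0.127 and 0.455 with an estimated correlation. The stria markers (3.08e-10) and macrophage markers (6.07e-05) passed with it too, at 0.0467 and 0.0362.

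**Figure D2:**
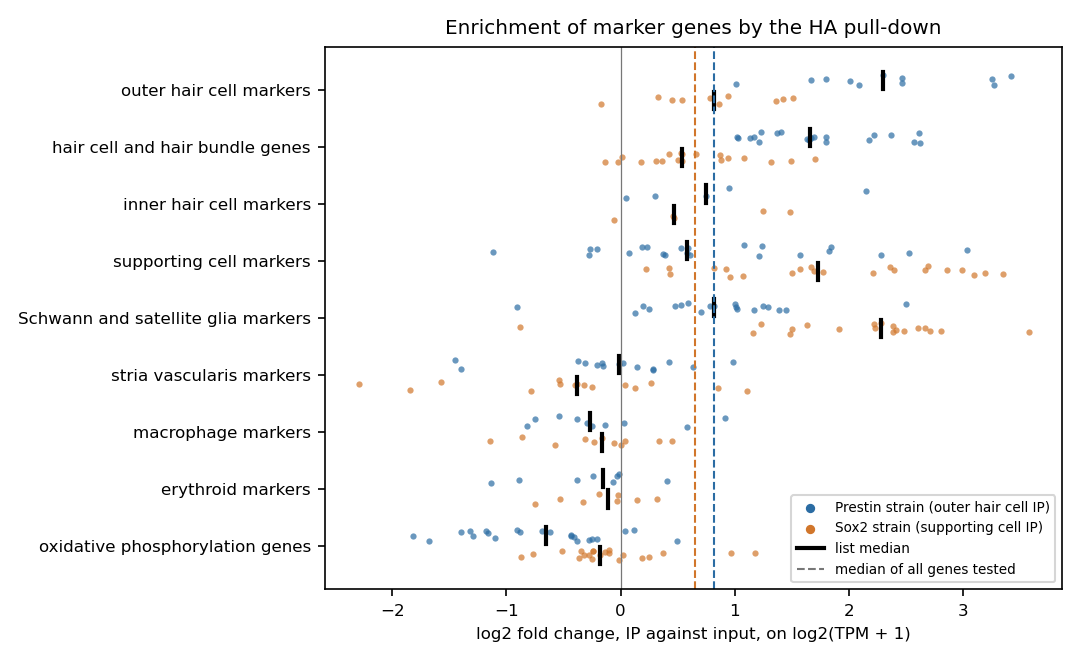
Enrichment of marker genes by the pull-downs. Each point is a gene, the x axis is its log2 fold change of IP against input, colour gives the strain, black bars are list medians and dashed lines the median of all genes tested. Outer hair cell markers have a median of 2.30 in the Prestin strain and 0.82 in the Sox2 strain, and supporting cell markers 0.59 and 1.73.

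The difference between both enrichments, a comparison added after the data were seen, parts the pull-downs along these cell types. Of 19648 genes, 4249 passed, 2751 more enriched in the outer hair cell IP and 1498 in the supporting cell IP, and 1477 and 1835 with median-of-ratios scaling. Of the shared genes, 194 with a mean of at least 5 TPM in the Prestin libraries were at 0 in all Sox2 libraries, and 69 the reverse. The filter did not leave such genes out of this or the other comparisons across strains. Their enrichment or response is 0 in the strain that lists them at 0. The median gene differed by 0.19. Of 11 outer hair cell markers, 10 were more enriched in the outer hair cell IP (median difference 1.10, adjusted p = 2.61e-09), led by Ocm (3.09 ± 0.26), Strc (2.81), Slc26a5 (2.63) and the cholinergic receptor Chrna9 (2.34). Of 21 hair bundle genes, 14 were (median 1.14, adjusted p = 7.9e-08), Lhfpl5 by 2.26 and Tmc1 by 1.36. Their adjusted p was 0.0763 with an estimated correlation. Of 22 supporting cell markers, 14 were more enriched in the supporting cell IP (median -1.12, adjusted p = 7.63e-16), with Sox2 at -2.66, Ceacam16 at -2.42, Otog at -2.10 and Bace2 at -1.35. Of 19 Schwann markers, 15 were (median -1.20, adjusted p = 4.45e-15), with Foxd3 at -3.32 and Cnp at -2.68. Adjusted over the list alone, the counts were 10, 14, 17 and 15, with 1 supporting cell marker on the other side. The named genes with the largest difference toward the supporting cell IP also included Igfbp6 (-4.23), Plbd1 (-3.25), Gfap (-3.16) and Sostdc1 (-2.96).

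At 6 h after noise, the whole cochlea showed an immediate early, chemokine and tissue repair response. Gdf15, a stress-induced cytokine, rose by 5.89 ± 0.37 (adjusted p = 5.35e-07), from 2.06 ± 1.47 to 223 ± 8.20 TPM in the Prestin inputs (n = 3 each) and from 6.35 ± 2.03 to 265 ± 34.6 TPM in the Sox2 inputs (n = 2 each). Gdf15 (ENSMUSG00000038508) lies on chromosome 8, from 70629393 to 70632456. Of 23 immediate early genes, 19 rose, the same number adjusted over the list alone, with a median of 1.36: Fos by 3.98 ± 0.28, Maff by 4.06 ± 0.23, Junb by 2.50 ± 0.17 and Dusp1 by 1.67 ± 0.13. Of 13 chemokines and cytokines, 7 rose and 6 did not pass, with 7 higher and 1 lower adjusted over the list alone. Ccl7 rose by 4.63, Ccl2 by 3.98 and Cxcl16 by 1.16. Of 17 STAT3 and acute phase genes, 10 rose (11 higher and 1 lower adjusted over the list alone), among them the feedback inhibitor Socs3 (3.09), Cebpd (1.72) and Cebpb (1.60). Of 17 matrix and wound genes, 13 rose (15 adjusted over the list alone), such as the protease Adamts1 (2.44), the growth factor Hbegf (2.07) and Ccn1 (1.55). Of 13 NF-kB targets, 6 rose (6 higher and 1 lower adjusted over the list alone), Bcl3 by 1.42, Nfkb2 by 1.05, Relb by 1.04 and Nfkbia by 0.59. Sprr1a, a gene of injured neurons and epithelia, rose by 3.34 and Hamp, the iron hormone hepcidin, by 3.32.

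Genes of stress programmes moved in the same libraries. Of 20 genes of the unfolded protein response, 9 rose (12 higher and 1 lower adjusted over the list alone), with the chaperones Hyou1 at 0.65, Hspa5 at 0.57 and Calr at 0.48. Of 14 heat shock genes, 8 rose (9 adjusted over the list alone), Hspb1 by 0.92. Of 13 p53 targets, 4 rose (5 adjusted over the list alone), Gadd45b by 1.91 and Cdkn1a by 0.75. Of 14 NRF2 genes, 6 rose, also 6 adjusted over the list alone, with Osgin1 at 1.78 and Gclc at 0.98. Their median was -0.05 while their mean was 0.27 and the test upward. Of 12 glucocorticoid-responsive genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with Pdk4 at 1.18, Sgk1 at 1.02 and Zbtb16 at -0.73. Of 29 interferon-stimulated genes, none rose and 5 fell (6 adjusted over the list alone), Ifit3 by -1.10 ± 0.25 and Dhx58 by -0.73 ± 0.19. Of 8 erythroid genes, 3 fell (5 adjusted over the list alone), among them Hba-a2 (-1.17) and Hba-a1 (-0.96). Large falls of named genes included the potassium channel subunit Kcnf1 (-1.96), Cdk19os (-1.79), Magee2 (-1.56) and Sox8, a factor of glia and supporting cells (-1.19).

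Of 14204 genes, 1213 passed at 6 h, 544 higher and 669 lower, and 783 without the Sox2 control input replicate 1. With median-of-ratios scaling the split was 796 higher and 429 lower. The immediate early (adjusted p = 3.22e-37), matrix (6.55e-20), STAT3 (1.91e-13), unfolded protein response (9.09e-13), chemokine (3.07e-09), NF-kB (1.42e-07) and p53 (2.4e-05) lists passed with an estimated correlation too, with adjusted p from 0.00144 to 0.00654. The heat shock (8.49e-06), glucocorticoid (5.52e-05), NRF2 (0.00209), erythroid (0.00455) and interferon (0.00657) lists did not, with adjusted p of 0.0943, 0.0624, 0.159, 0.383 and 0.744 with an estimated correlation. In the Prestin inputs alone 661 genes passed, 352 higher and 309 lower, against 463 and 217 with median-of-ratios scaling. That count fell to 286 and 373 without 6 h replicates 1 and 3, and to 292, 373 and 307 without control replicates 1, 2 and 3. In the Sox2 inputs alone 151 genes passed, 46 higher and 105 lower, and 0 without control replicate 1, 6 without control replicate 4 and 2057 without 6 h replicate 2.

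At 24 h, the whole cochlea response was led by interferon, chemokine, STAT3 and antigen presentation genes. All 29 interferon-stimulated genes rose, also when adjusted over the list alone, with a median of 1.45, among them Gbp2 (2.74 ± 0.18), Zbp1 (2.31 ± 0.21), Iigp1 (2.30 ± 0.24) and Ifit1 (1.87 ± 0.18). Cxcl10, an interferon-induced chemokine for T cells, rose by 4.49 ± 0.40 (adjusted p = 1.46e-05), from 8.02 ± 6.98 to 220 ± 108 TPM in the Prestin inputs and from 12.9 ± 10.4 to 199 ± 48.0 TPM in the Sox2 inputs. Cxcl10 (ENSMUSG00000034855) lies on chromosome 5, from 92346638 to 92348889. Of 13 chemokines and cytokines, 9 rose (12 adjusted over the list alone), including Ccl2 (4.35), Ccl7 (4.19) and Ccl5 (3.20). Of 14 antigen presentation genes, 10 rose, also 10 adjusted over the list alone, with Tap1 at 1.31, H2-K1 at 1.03, H2-D1 at 0.88 and Tapbp at 0.83. Of 10 macrophage markers, 4 rose (6 adjusted over the list alone): the lysosomal protein Cd68 by 3.15 ± 0.26, Fcgr1 by 1.13, C1qb by 0.99 and C1qa by 0.69. Of 17 STAT3 genes, 12 rose (13 higher and 1 lower adjusted over the list alone), with Socs3 at 2.12 and Stat3 at 0.80, and of 13 NF-kB targets 6 rose (7 adjusted over the list alone), with Icam1 at 2.13. Timp1, an inhibitor of matrix proteases, rose by 3.81 ± 0.28. Of 23 immediate early genes, 5 rose (10 higher and 2 lower adjusted over the list alone), with Junb at 1.40 and Maff at 1.38. The falls were of the calcium-binding protein S100b (-1.09), Otos, a product of fibrocytes (-1.08), the lens crystallin Crygn (-0.99) and the transferrin receptor Tfrc (-0.87).

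Of 14204 genes, 631 passed at 24 h, 537 higher and 94 lower. The interferon (adjusted p = 7.42e-48), chemokine (2e-17), STAT3 (2e-17), antigen presentation (2.15e-14), NF-kB (3.85e-08) and macrophage (4.22e-06) lists passed with an estimated correlation too, with adjusted p from 0.00105 to 0.00435. The immediate early list (adjusted p = 0.000196) did not, with an adjusted p of 0.206 with an estimated correlation. In the Prestin inputs alone 733 genes passed, 445 higher and 288 lower, against 533 and 265 with median-of-ratios scaling. Without 24 h replicates 1, 2 and 3 in turn, 199, 206 and 389 passed, and 256 and 245 without control replicates 1 and 3. There, 6 of 15 neuron markers (12 adjusted over the list alone, median -0.87, adjusted p = 1.73e-09, adjusted p = 0.186 with an estimated correlation) fell. In the Sox2 inputs alone limma called 0 of 15371 genes, with 1190 at an unadjusted p under 0.05. The genes with the smallest p there included Sfrp4 (1.75, adjusted p = 0.0864), Socs3 (2.19, 0.087) and Ifitm1 (2.12, 0.087). That count was 3, 4 and 1 without 24 h replicates 1, 2 and 3.

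**Figure D3:**
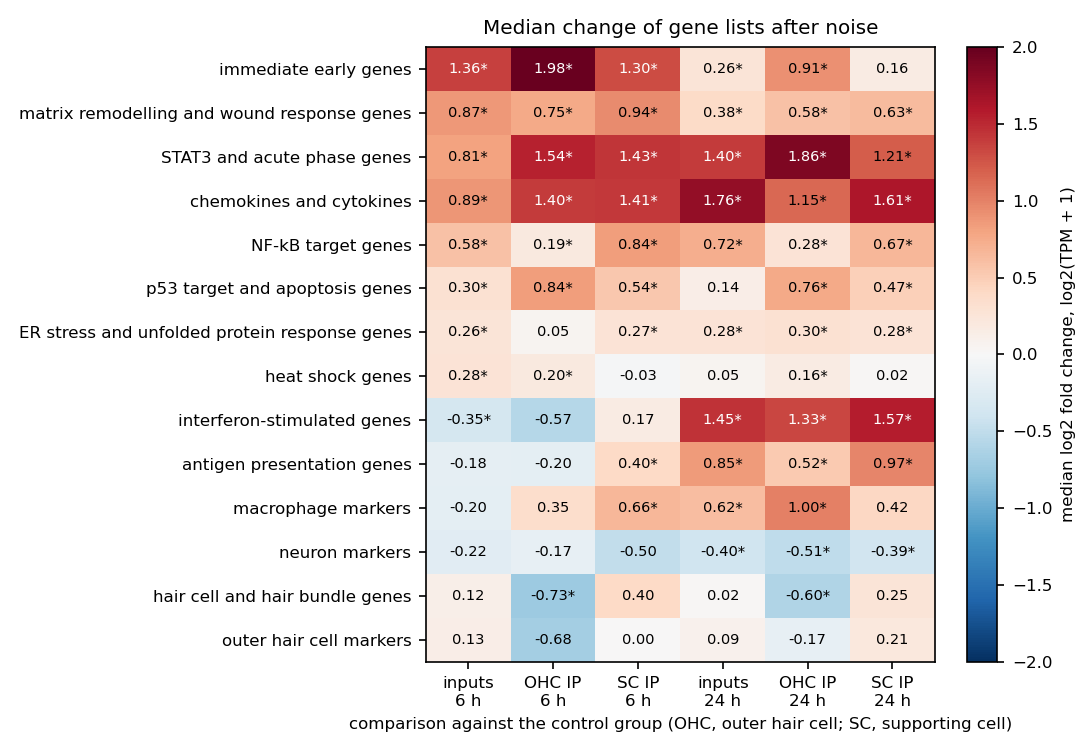
Median log2 fold change of 14 gene lists in the inputs of both strains and in the outer hair cell and supporting cell IPs, against the control group at each time. Colour and number give the median on the log2(TPM + 1) scale, and an asterisk marks an adjusted p under 0.05 in camera with the preset correlation. Immediate early genes have medians of 1.36, 1.98 and 1.30 at 6 h, and interferon-stimulated genes 1.45, 1.33 and 1.57 at 24 h.

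In the outer hair cell IP at 6 h, 143 genes were higher, among them immediate early, chemokine and STAT3 genes, whose lists had adjusted p = 0.129, 0.152 and 0.129 with an estimated correlation. Gdf15 rose by 6.35 ± 0.81 (adjusted p = 0.0131), from 7.26 ± 8.94 to 442 ± 73.5 TPM (n = 3 each). Of 23 immediate early genes, 15 rose (18 adjusted over the list alone), with a median of 1.98, which is 2.15 above the median gene: Fos by 3.99 ± 0.58, Maff by 3.48 ± 0.32, Junb by 2.58 ± 0.26 and Atf3 by 2.39 ± 0.26. Of 17 chemokines and cytokines, 5 rose (9 adjusted over the list alone): Ccl2 by 5.20, Ccl7 by 4.97, Cxcl10 by 2.67 and Lif by 2.05, while Cxcl1 was listed at 0 in all control IPs and at 17.3 ± 3.67 TPM at 6 h. Of 17 STAT3 genes, 9 rose (10 adjusted over the list alone), among them Socs3 (3.50), Bcl3 (2.37) and Myc (1.98). Of 19 matrix and wound genes, 4 rose (7 adjusted over the list alone), including Adamts1 (1.33) and Ccn1 (1.05). Of 14 heat shock genes, 2 rose (4 higher and 1 lower adjusted over the list alone), the inducible chaperones Hspa1a (1.84) and Hspa1b (1.56). Sprr1a was listed at 0 in the control IPs and at 37.3 ± 6.21 TPM at 6 h. Of 20 hair bundle genes, 1 fell (3 adjusted over the list alone), with a median of -0.73, which is 0.56 below the median gene (-0.56, adjusted p = 0.0167, adjusted p = 0.772 with an estimated correlation). Without Prestin control IP replicate 1 the list median was -0.46. The gene that fell was Gfi1, a transcription factor that hair cells need, at -1.73 ± 0.36, from 25.8 ± 2.24 to 7.75 ± 3.96 TPM. Myo15 (-0.85, adjusted p = 0.0568) and Ush1c (-1.15, adjusted p = 0.0735) did not pass. Large falls of named genes were of little-studied genes, such as Adam4 (-2.99), Fem1al (-2.80) and Ctla2b (-2.67), and of the potassium channel Kcna7 (-2.50). Ccdc78, Hm629797 and Tpi-rs2 were listed at 0 at 6 h, from 5.15 ± 2.86, 8.74 ± 4.16 and 16.3 ± 13.1 TPM.

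Of 16703 genes, 940 passed in this comparison, 143 higher and 797 lower. The median gene was lower by 0.17 (-0.17), and with median-of-ratios scaling 307 genes passed, 137 higher and 170 lower. The control IPs listed 44030 to 73023 TPM of the nuclear RNA Malat1, against 12251 to 22823 in the noise IPs of both times. Mitochondrially encoded genes held 4.91% to 8.40% of the TPM in the control IPs, 10.6% to 13.7% at 6 h and 7.40% to 13.1% at 24 h. Without control replicates 1 and 3, 245 and 188 genes passed, and 81, 132 and 275 without 6 h replicates 1, 2 and 3. The immediate early (adjusted p = 3.87e-22), STAT3 (1.54e-10), chemokine (1.95e-10), matrix (1.03e-08), heat shock (0.00269) and hair bundle (0.0167) lists passed. Their adjusted p were 0.129, 0.129, 0.152, 0.129, 0.451 and 0.772 with an estimated correlation.

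At 24 h, 183 genes were higher in the outer hair cell IP, among them interferon, chemokine, STAT3 and antigen presentation genes. In camera, each of these lists had an adjusted p of 0.219 with an estimated correlation. These rises cannot be assigned to outer hair cells alone, since RNA of other cells was present in this IP. Relative to the input response, 14 genes were higher and 167 lower in this IP at 24 h. Cxcl10 rose by 5.80 ± 0.30 (adjusted p = 0.000476), from 8.88 ± 1.77 to 577 ± 252 TPM (n = 3 each). Of 29 interferon-stimulated genes, 10 rose (22 adjusted over the list alone), with a median of 1.33, which is 1.48 above the median gene: Rsad2 by 3.27, Iigp1 by 2.90, Ifit1 by 1.74 and Irgm1 by 1.44. Of 17 chemokines and cytokines, 6 rose (9 adjusted over the list alone), including Ccl2 (5.79), Ccl7 (5.01) and Ccl5 (4.63). Of 17 STAT3 genes, 11 rose (12 adjusted over the list alone), such as Serpina3n (2.82), Bcl3 (2.18) and Osmr (1.86). Of 14 antigen presentation genes, 3 rose (5 adjusted over the list alone): Psmb8 by 1.75, B2m by 1.66 and Tapbp by 1.46. The immune checkpoint ligand Cd274 rose by 3.07. Glycam1 and Sprr1a were listed at 0 in the control IPs and at 21.7 ± 8.39 and 8.83 ± 7.59 TPM at 24 h. Of 10 macrophage markers, 1 rose (5 adjusted over the list alone), Mpeg1 by 1.65, with a list median of 1.0, and Cd68 was at 3.33 (adjusted p = 0.0563). Of 20 hair bundle genes, 1 fell (4 adjusted over the list alone), Myo15 by -0.96 ± 0.21, with a list median of -0.60, which is 0.45 below the median gene (-0.45, adjusted p = 0.00944, adjusted p = 0.531 with an estimated correlation). Without Prestin control IP replicate 1 the list median was -0.34. Ush1c (-1.27, adjusted p = 0.0572), Lhx3 (-1.10, 0.0632) and Ocm (-0.77, 0.232) did not pass. The noncoding RNA Miat fell by -2.66, and also fell in the Prestin inputs (-1.75). Other large falls were of Ldhal6b (-4.01), Adam4 (-3.01), Fem1al (-2.99) and the semaphorin receptor Plxnb3 (-2.37), and Nanos2 was listed at 0 at 24 h, from 8.79 ± 1.58 TPM.

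Of 16703 genes, 1041 passed at 24 h, 183 higher and 858 lower. The median gene was lower by 0.15 (-0.15), and with median-of-ratios scaling 573 passed, 233 higher and 340 lower. Without 24 h replicates 1, 2 and 3 in turn 70, 73 and 121 genes passed, and 456 and 260 without control replicates 1 and 3. The interferon (adjusted p = 4.69e-17), STAT3 (2.2e-12), chemokine (1.08e-10), antigen presentation (6.95e-06), macrophage (0.000351) and hair bundle (0.00944) lists passed. With an estimated correlation the adjusted p was 0.531 for the hair bundle genes and 0.219 for the others. Between both times, 52 genes were higher at both 6 h and 24 h, against 1.57 for independent lists, and 448 lower, against 40.9, with 0 in opposite directions. Unchanged groups simulated against the same controls shared 0.01 calls on average and at most 1. Simulated sets without any change gave at most 1 call at 6 h and 0 at 24 h. A shared count near 0 therefore cannot show what the shared controls add. The 3 control IPs cannot be divided into 2 parts of at least 2, so part of the excess of shared calls may come from the shared controls.

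In the supporting cell IP at 6 h, 38 genes were higher, among them 6 immediate early and 4 STAT3 genes, and both lists had an adjusted p of 0.203 with an estimated correlation. Gdf15 rose by 5.43 ± 0.56 (adjusted p = 0.0254), from 9.38 ± 3.77 to 448 ± 172 TPM (n = 2 each), and Ccl2 by 5.01 ± 0.33 (adjusted p = 0.00975). Of 23 immediate early genes, 6 rose (16 adjusted over the list alone), with a median of 1.30: Maff by 4.08, Atf3 by 3.22, Junb by 1.85 and Zfp36, which speeds the decay of cytokine mRNAs, by 1.32. Of 18 STAT3 genes, 4 rose (10 higher and 1 lower adjusted over the list alone), including Socs3 (3.12), Cebpd (2.70) and Pim1 (1.96). Of 16 chemokines and cytokines, 1 rose (5 higher and 1 lower adjusted over the list alone), Ccl2, and Ccl7 was at 5.22 (adjusted p = 0.0618). Of 19 matrix and wound genes, 0 passed in limma over all genes and 10 rose adjusted over the list alone (median 0.94). Further rises were of Gem (5.17), the chloride channel protein Clic3 (4.29), the TWEAK receptor Tnfrsf12a (3.49) and the ephrin receptor Epha2 (3.13). The largest falls of named genes that passed were of Pnck (-4.78), Pnma2 (-4.52), Ndufa4l2 (-4.18), Necab2 (-4.06), Rec8 (-4.03), Bex2 (-3.90), Zfp428 (-3.64) and Nrsn2 (-3.55). Neuron markers did not pass as a list (median -0.50, adjusted p = 0.239). Hes5, a Notch target of supporting cells, was at -4.83 ± 1.28 and did not pass (adjusted p = 0.141).

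Of 17577 genes, 122 passed, 38 higher and 84 lower. Without control replicates 1 and 4, 60 and 4 genes passed, and 75 and 31 without 6 h replicates 2 and 4. The 6 h IPs listed 16537 and 16813 genes above 0, and the control IPs 17395 and 19230. Mitochondrially encoded genes held 8.83% and 7.21% of the TPM in the 6 h IPs and 3.07% and 4.35% in the control IPs. The immediate early (adjusted p = 8.28e-15), STAT3 (8.56e-09), matrix (2.51e-06) and chemokine (0.000549) lists passed, each with an adjusted p of 0.203 with an estimated correlation.

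At 24 h, 19 genes were higher in the supporting cell IP, among them 1 interferon-stimulated gene and 2 chemokines, and both lists had an adjusted p of 0.0876 with an estimated correlation. Ccl2 rose by 4.65 ± 0.30 (adjusted p = 0.013) and Cxcl10 by 4.64 ± 0.31, from 12.3 ± 3.14 (n = 2) to 337 ± 103 TPM (n = 3). Lcn2, an iron-sequestering protein of the acute phase, was listed at 0 in the control IPs and at 19.3 ± 8.80 TPM at 24 h. Of 29 interferon-stimulated genes, 1 rose over all genes and 24 adjusted over the list alone, with a median of 1.57, which is 1.43 above the median gene. That gene was Stat2 (1.52 ± 0.16), while Rsad2 (3.15, adjusted p = 0.0722) and Oasl2 (1.90, 0.064) did not pass. The interferon-induced Ifi44l (2.89) and Ifitm3 (2.11), outside that list, rose too. Of 16 chemokines and cytokines, 2 rose (9 higher and 1 lower adjusted over the list alone), Ccl2 and Cxcl10. Of 18 STAT3 genes, 1 rose (11 adjusted over the list alone), and Socs3 was at 2.46 (adjusted p = 0.0597). Of 14 antigen presentation genes, 0 passed over all genes in limma and 9 rose adjusted over the list alone (median 0.97), with Psmb8 at 2.16 (adjusted p = 0.0858) and Tap1 at 1.59 (0.109). The 1 named fall was of the neuronal gene Ncdn (-1.56 ± 0.17). Otog (1.11, adjusted p = 0.261) and Gjb2, the gap junction protein connexin 26 (0.67, 0.274), did not pass.

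Of 17577 genes, 33 passed, 19 higher and 14 lower. The median gene was higher by 0.14, and with median-of-ratios scaling 13 were higher and 12 lower. With that scaling 4 of the 7 called genes named for this comparison lost their calls. Without control replicate 4 limma called 0 genes, and without 24 h replicate 1 it called 3. Bpifa1, an airway epithelium gene, stood at 4029, 401 and 12740 TPM in 24 h replicates 1, 2 and 3 and at 313 and 189 TPM in the control IPs, so 24 h replicates 1 and 3 stand apart in this gene. The interferon (adjusted p = 1.9e-21), antigen presentation (1.59e-08), STAT3 (2.15e-07) and chemokine (1.85e-05) lists passed, with adjusted p = 0.0876, 0.0876, 0.236 and 0.0876 with an estimated correlation.

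**Figure D4:**
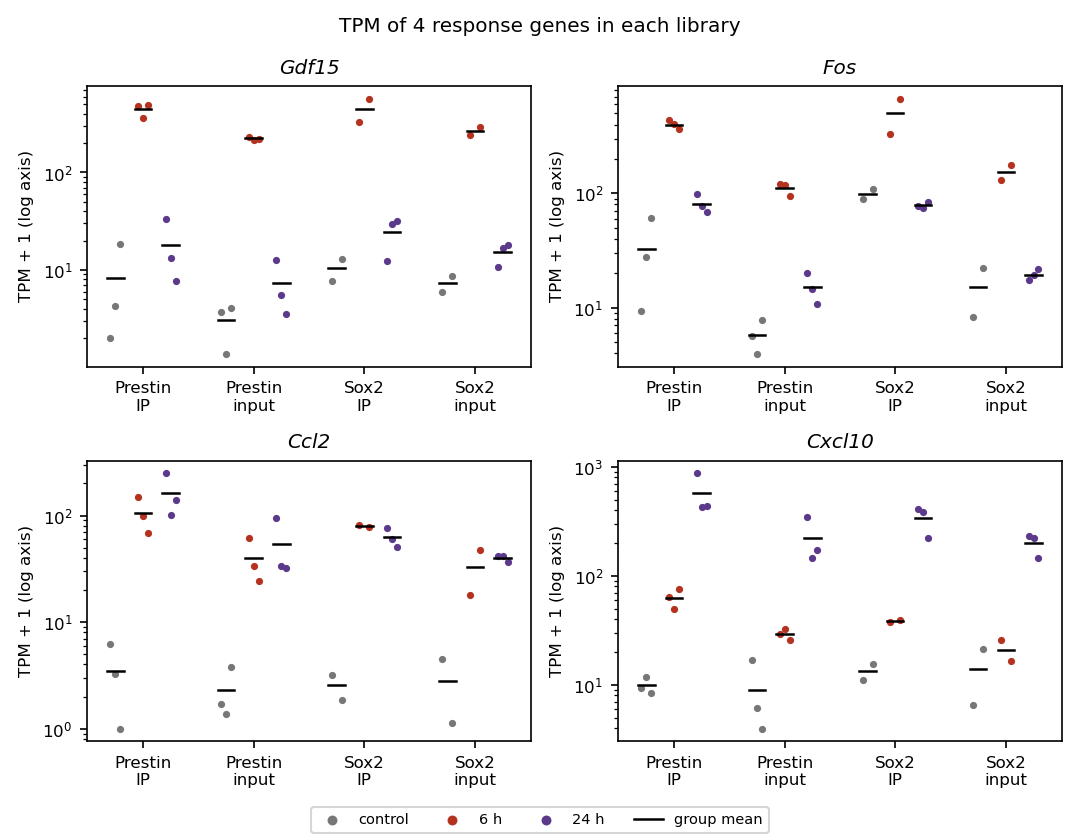
TPM of Gdf15, Fos, Ccl2 and Cxcl10 in each library of the 4 kinds, on a log axis of TPM + 1. Points are libraries, grey for control, red for 6 h and purple for 24 h, and bars are group means. Gdf15 stood at 442 TPM at 6 h in the outer hair cell IP and 448 in the supporting cell IP, and Cxcl10 at 577 and 337 TPM at 24 h.

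The time course was tested as 24 h against 6 h. In the inputs 2284 genes passed, 1790 higher and 494 lower at 24 h, and 1040 and 810 with median-of-ratios scaling. All 29 interferon-stimulated genes were higher at 24 h (median 1.88, adjusted p = 8.37e-32), also adjusted over the list alone, with Ifit3 at 3.04. Of 23 immediate early genes, 21 were lower (median -1.17, adjusted p = 8.37e-32), also 21 adjusted over the list alone, with Fos at -2.97 and Gem at -3.13. Gdf15 was lower by -4.73. Of 10 macrophage markers, 7 were higher (9 adjusted over the list alone, median 0.95). These 3 lists passed with an estimated correlation too, at adjusted p of 0.0324, 0.00313 and 0.00689. In the outer hair cell IP 17 genes passed, with Mx1 at 3.69, Cxcl10 at 3.13 and Gem at -2.34, and in the supporting cell IP 89 passed, 77 higher and 12 lower, with Cxcl10 at 3.08, Fos at -2.57 and Gdf15 at -4.25. With median-of-ratios scaling, the supporting cell split was 33 and 10. There Ccl12 was listed at 0 at 6 h and at 21.7 ± 11.5 TPM at 24 h. In the outer hair cell IP, 2 of 29 interferon-stimulated genes were higher (29 adjusted over the list alone, median 1.64, adjusted p = 6.11e-41, adjusted p = 0.194 with an estimated correlation). In the supporting cell IP, 1 was (23 adjusted over the list alone, median 1.62, adjusted p = 2.75e-17, adjusted p = 0.197 with an estimated correlation). Immediate early genes had medians of -0.91 (adjusted p = 5.01e-18, adjusted p = 0.2 with an estimated correlation) and -1.22 (adjusted p = 4.43e-31, adjusted p = 0.197 with an estimated correlation). The 17 genes fell to 3 without 24 h replicate 1 and to 0 without each of the other 5 libraries, with 1328 at an unadjusted p under 0.05 in limma over all libraries. The 89 fell to 0, 29 and 21 without 24 h replicates 1, 2 and 3, and to 46 and 12 without 6 h replicates 2 and 4.

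In the inputs, 155 genes were higher at both times, against 20.6 for independent lists, and 28 lower, against 4.43, while 36 went in opposite directions. Unchanged groups simulated against the same controls shared 0 calls. Simulated sets without any change gave at most 1 call at either time, so this cannot show what the shared controls add. With the 5 controls divided into 3 for 6 h and 2 for 24 h, 44 genes were higher at both times, against 3.37, and with the parts exchanged 45, against 3.98. Only 3 genes were then lower at both times, against 0.253, and 4 with the parts exchanged, against 0.332.

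Whether a pull-down responded differently from its own input was tested as an interaction. In the outer hair cell IP at 6 h, 420 of 17363 genes differed, 26 higher and 394 lower relative to the input, and 28 with the homogenate as a block. With median-of-ratios scaling the split was 13 and 34. B2m, the light chain of class I molecules, was higher in the IP by 0.96 ± 0.22, the osteocalcin gene Bglap2 by 2.95 and Snai3 by 2.24, while Fem1al differed by -2.60 ± 0.36. Fem1al was listed at 0 in the 6 h inputs, so the size of this value on the log2(TPM + 1) scale is set by the pseudocount. With a pseudocount of 0.1 all of these genes lost their calls (adjusted p = 0.0605 for B2m, 0.0513 for Bglap2, 0.0648 for Snai3 and 0.148 for Fem1al). B2m (adjusted p = 0.15) and Bglap2 (0.111) also lost them without 6 h homogenate 1. Hair bundle genes had a median difference of -0.76 (1 of 20 lower, 5 adjusted over the list alone, adjusted p = 0.00271) and p53 targets of 0.42 (0 of 16 in limma, adjusted p = 0.0101), both with an adjusted p of 0.84 with an estimated correlation. The count was 32, 819 and 60 without control homogenates 1, 2 and 3, and 41, 82 and 220 without 6 h homogenates 1, 2 and 3. At 24 h 181 genes differed, 14 higher and 167 lower, and 20 with the block, with B2m at 1.03, Bglap2 at 2.79, Mgat2 at 1.0, Plxnb3 at -2.13 and Il18bp, which rose in the input, at -2.07. All of these lost their calls with a pseudocount of 0.1 (adjusted p = 0.0891 each) and without 24 h homogenate 2 (from 0.135 for Plxnb3 to 0.196 for Il18bp). With median-of-ratios scaling the split was 4 and 20. The count was 15, 413 and 44 without control homogenates 1, 2 and 3, and 21, 25 and 48 without 24 h homogenates 1, 2 and 3.

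In the supporting cell IP at 6 h, 50 of 18560 genes differed from the input, 24 higher and 26 lower, and 3 with the homogenate as a block. Clic3 differed by 5.30, the neutrophil granule gene Ngp by 6.14, Ndufa4l2 by -4.09, the growth factor Mdk by -2.06 and Cpt1c by -2.22. All of these lost their calls without control homogenate 4 (adjusted p from 0.0863 for Mdk to 0.192 for Ngp), and with the block only Clic3 kept its call. The count was 454 without 6 h homogenate 2 and 4 without control homogenate 4. At 24 h 9 genes differed, 3 higher and 6 lower, and 2 with the block, and none of the 9 met the conditions for naming. With median-of-ratios scaling the split was 1 and 5. The count was 16, 34 and 18 without 24 h homogenates 1, 2 and 3, and 31 without control homogenate 1.

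The responses of both pull-downs differed in 98 of 18997 genes at 6 h, 64 higher and 34 lower in the outer hair cell IP. With median-of-ratios scaling 115 were higher and 33 lower. Clic3 differed by -5.63 ± 0.52, from 14.7 ± 1.16 to 5.38 ± 2.07 TPM in the outer hair cell IP and from 0.360 ± 0.508 to 24.6 ± 1.09 TPM in the supporting cell IP. Bglap2 (6.17), the orphan receptor Gpr25 (7.04) and the neuropeptide precursor Vgf (5.39) differed the other way, and Vgf stood at 149 ± 21.1 TPM in the control supporting cell IPs and 1.70 ± 0.687 at 6 h. Clic3 kept its call in every alternative, while without the Sox2 control IP replicate 4 Vgf (adjusted p = 0.122) and Bglap2 (0.053) lost theirs, as did Gpr25 (0.102) without the Prestin 6 h IP replicate 3. The count was 53 without the Prestin 6 h IP replicate 3, 306 without the Sox2 6 h IP replicate 2 and 230 without the Sox2 control IP replicate 1. At 24 h 32 genes differed, 8 higher and 24 lower. The median gene differed by -0.27, and with median-of-ratios scaling 10 were higher and 17 lower. Clic3 (-2.93), the copper chaperone Cox17 (-2.34) and Gstm5 (1.63) were among them, and lost their calls without the Prestin 24 h IP replicate 3 (adjusted p = 0.102, 0.0994 and 0.103). The count was 20 without the Prestin 24 h IP replicate 3, 55, 66 and 59 without Prestin control IPs 1, 2 and 3, 57 without the Sox2 24 h IP replicate 2 and 220 without the Sox2 control IP replicate 1. Hair bundle genes had median differences of -0.81 at 6 h (adjusted p = 0.00768, adjusted p = 0.772 with an estimated correlation) and -0.64 at 24 h (adjusted p = 0.0393, adjusted p = 0.741 with an estimated correlation).

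The input responses of the strains differed in 164 of 16041 genes at 6 h, 143 higher and 21 lower in the Prestin strain. The Sox2 6 h inputs listed 16966 and 15929 genes above 0, and the other Sox2 inputs 19748 to 21239. Of 105 genes called lower in the Sox2 inputs at 6 h, 50 had a called difference between strains. Whether depth or shared reads lowered them stays open, so these differences need not be responses to noise. Hes5 differed by 3.47 ± 0.51. It stood at 16.2 ± 0.674 TPM in the Sox2 control inputs and 0.115 ± 0.163 at 6 h, against 3.36 ± 1.60 and 2.10 ± 1.05 TPM in the Prestin inputs. With so low a level at 6 h, the size of this difference depends on the pseudocount. H3c15 (4.23) and the protocadherin Pcdh8 (3.15) differed the same way, and Slitrk6 (-1.67), Dhh, a signal of Schwann cells (-1.43), Hsf4 (-2.05) and Ripk1, a kinase of cell death signalling (-0.98), the other way. Only H3c15 kept its call in every alternative, and without the Sox2 control input replicate 1 the adjusted p was 0.0876 for Pcdh8 and Dhh, 0.119 for Slitrk6, 0.0921 for Hsf4 and 0.109 for Ripk1. The count was 73, 85 and 87 without Prestin control inputs 1, 2 and 3, 79 and 87 without Prestin 6 h inputs 2 and 3, 2103 and 263 without Sox2 6 h inputs 2 and 4, and 76 without the Sox2 control input replicate 1. At 24 h 1 gene differed, Mir3074-1 (3.45). The count was 0 and 2 without Prestin 24 h inputs 1 and 2, 2, 2 and 4 without Prestin control inputs 1, 2 and 3, 2, 3 and 16 without Sox2 24 h inputs 1, 2 and 3, and 39 without the Sox2 control input replicate 1. Neuron markers had a median difference of -0.96 at 24 h (0 of 16 over all genes in limma and 9 lower adjusted over the list alone, adjusted p = 1.79e-08, adjusted p = 0.288 with an estimated correlation).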

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

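Of the tests in this part, the difference between the enrichments and the tests on untagged cell types, transcript length, the range of cell type medians and hair cell genes in the inputs were chosen after the results were seen, and so was the weight given to both tests of depth; the removal of the GC trend and the fit without Prestin control IP replicate 1 were added after the data were seen but before their own values were. Each result of the next paragraphs is here because a test found that 2 groups of libraries differed in their response or enrichment.

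The outer hair cell IP and its input responded differently in 420 genes at 6 h, 28 with the homogenate as a block and 47 with median-of-ratios scaling. The median difference was -0.76 in hair bundle genes (adjusted p = 0.00271) and 0.42 in p53 targets (0.0101), and both had an adjusted p of 0.84 with an estimated correlation. B2m differed by 0.96, Bglap2 by 2.95 and Snai3 by 2.24. Ccdc78 (-2.81) and Hm629797 (-3.32) were listed at 0 in the 6 h IP and Fem1al (-2.60) at 0 in the 6 h input, so these 3 values on the log2(TPM + 1) scale are set in size by the pseudocount. At 24 h 181 genes differed, 20 with the block and 24 with median-of-ratios scaling. Hair bundle genes had a median difference of -0.49 (adjusted p = 0.00844), ion transport genes of 0.52 (0.00412) and neutrophil markers of 0.66 (0.00841), all with an adjusted p of 0.703 with an estimated correlation. B2m was at 1.03, Bglap2 at 2.79, Mgat2 at 1.0, Plxnb3 at -2.13, Il18bp at -2.07, the smooth muscle RNA Carmn at -1.68 and Fem1al, listed at 0 in the 24 h input, at -2.80 with a size set by the pseudocount. In the supporting cell IP 50 genes differed from the input at 6 h, 3 with the block, with medians of 0.48 in ion transport genes (adjusted p = 0.000254), 0.68 in macrophage markers (0.0124) and 0.67 in interferon-stimulated genes (0.0124). With an estimated correlation their adjusted p were 0.104, 0.104 and 0.818. Clic3 was at 5.30, Ngp at 6.14, Ndufa4l2 at -4.09, Mdk at -2.06 and Cpt1c at -2.22. At 24 h 9 genes differed, 2 with the block, with medians of 0.38 in ion transport (adjusted p = 0.00092) and -0.18 in oxidative phosphorylation genes (0.00653). Their adjusted p were 0.374 and 0.976 with an estimated correlation.

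Between 6 h and 24 h, 17 genes differed in the outer hair cell IP, with medians of -0.91 in immediate early (adjusted p = 0.2 with an estimated correlation) and 1.64 in interferon-stimulated genes (0.194), and with Mx1 at 3.69, Cxcl10 at 3.13 and Gem at -2.34. In the supporting cell IP 89 differed, with list medians of -1.22 and 1.62 (adjusted p = 0.197 with an estimated correlation for both), and with Cxcl10 at 3.08, Gdf15 at -4.25 and Fos at -2.57. Ccl12 was listed at 0 at 6 h, and its value of 4.36 is set in size by the pseudocount. In the inputs 2284 differed: immediate early genes had a median of -1.17, interferon-stimulated genes of 1.88 and macrophage markers of 0.95 (adjusted p = 0.00313, 0.0324 and 0.00689 with an estimated correlation), with Glycam1 at 3.93, Ifit3 at 3.04, Cxcl10 at 2.99, Gdf15 at -4.73, Gem at -3.13 and Fos at -2.97.

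The pull-downs differed from each other in 98 genes at 6 h. Hair bundle genes had a median difference of -0.81, Schwann markers of -0.64 and interferon-stimulated genes of -0.56 (adjusted p = 0.00768, 0.00811 and 0.00768), all with an adjusted p of 0.772 with an estimated correlation. Bglap2 was at 6.17, Vgf at 5.39, Gpr25 at 7.04 and Clic3 at -5.63. The values of Dio3 (6.30), Tnfsf9 (4.98) and Apom (-2.83) are set in size by the pseudocount, since Dio3 was listed at 0 in the control outer hair cell IP, Tnfsf9 in the 6 h supporting cell IP and Apom in 2 of the 4 groups. At 24 h 32 genes differed, with medians of -0.64 in hair bundle, 0.94 in immediate early, 0.66 in chemokine and 0.26 in oxidative phosphorylation genes (adjusted p = 0.0393, 7.98e-06, 0.0393 and 0.000731), all with an adjusted p of 0.741 with an estimated correlation. Clic3 was at -2.93, Cox17 at -2.34 and Gstm5 at 1.63, and Dio3 (5.90) and Npy2r (3.37), both listed at 0 in the control outer hair cell IP, had sizes set by the pseudocount. The inputs of the strains differed in 164 genes at 6 h, with medians of -0.22 in Schwann and -0.35 in neuron markers (adjusted p = 0.0272 and 0.0275, both with an adjusted p of 0.937 with an estimated correlation). Hes5 was at 3.47, H3c15 at 4.23, Pcdh8 at 3.15, Slitrk6 at -1.67, Dhh at -1.43, Hsf4 at -2.05 and Ripk1 at -0.98. The size for Hes5 depends on the pseudocount, since its level in the Sox2 6 h inputs was low. At 24 h 1 gene differed, while neuron markers had a median of -0.96, Schwann markers of -0.54, erythroid markers of -0.76, neutrophil markers of -1.16, fibrocyte markers of 0.22 and stria markers of 0.20. None of these lists passed with an estimated correlation, where the adjusted p were 0.288, 0.333, 0.288, 0.382, 0.288 and 0.288.

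The enrichments differed in 4249 genes. Medians were 1.10 in outer hair cell markers, 1.14 in hair bundle genes, -1.12 in supporting cell markers, -1.20 in Schwann markers, -0.67 in oxidative phosphorylation genes and 0.49 in endothelial markers. With an estimated correlation the adjusted p was 0.0763 for hair bundle genes and 0.211 for endothelial markers, which lost their calls. Ocm was at 3.09, Strc at 2.81, Slc26a5 at 2.63, Chrna9 at 2.34, Lhfpl5 at 2.26 and Tmc1 at 1.36. Toward the supporting cell IP lay Sox2 (-2.66), Ceacam16 (-2.42), Otog (-2.10), Bace2 (-1.35), Cnp (-2.68), Foxd3 (-3.32), Igfbp6 (-4.23), Plbd1 (-3.25), Sostdc1 (-2.96) and Gfap (-3.16).

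The enrichments of the pull-downs correlated with r = 0.719 across 16170 genes. Once trends on transcript length, GC content and exon number were removed, r was 0.688, which argues against these properties as the main source. Markers of untagged cells (stria, macrophage, neutrophil and erythroid) lay below the median gene, by -0.88 in the outer hair cell IP and -0.82 in the supporting cell IP. The median gene itself was higher by 0.82 in the outer hair cell IP and 0.65 in the supporting cell IP. These markers thus stood near their input share, and their RNA was present in both IPs. The test cannot tell how it came there or how much of the correlation it explains.

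In the Sox2 inputs at 6 h 105 genes were called lower; the 83 of them tested in the Prestin inputs had a median of -0.10 there, against -2.52, which argues against a noise response shared by the strains. Once each library's trend on GC was removed 67 stayed called, and the median of the 105 went from -2.60 to -2.38 (median SE 0.28 both times). The other 38 lost their calls as their median went from -1.86 to -1.69, with a median SE of 0.25 both times. That leaves open whether GC played a part. The median GC content of the 105 was 50.6%, against 50% in all genes tested, and most of their median fall remained without the trend. Lower depth stays open too: 35.2% were at 0 in both 6 h inputs but only 8.57% were also at 5 TPM or less in controls, while their transcripts were short for their level (0.319 of that of genes matched on control TPM). Of the 105, 42 are protein coding and 35 pseudogenes, while 78.9% of tested genes are protein coding; reads shared between copies and a noise response in the Sox2 strain alone were not tested, and depth is not known from TPM.

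Hair bundle genes had a median of -0.60 in the outer hair cell IP at 24 h, though only 1 of 20 passed (adjusted p = 0.531 for the list with an estimated correlation), while outer hair cell markers were at -0.17. A smaller share of outer hair cell RNA in the noise IPs would raise the other cell types alike, if these did not change themselves. Their medians spanned 1.5 over 11 cell types, from -0.51 in neuron to 1.0 in macrophage markers (permutation p = 8e-04, 10000 resamples of genes between lists). But macrophage markers also rose in the inputs at 24 h, and neuron markers fell in the Prestin inputs. Such changes would part the medians with or without a smaller share, so this test cannot decide. In the Prestin inputs the hair bundle genes tested there had a median of 0.01, which argues against a broad loss of hair cell RNA from the cochlea. The list is not particular to outer hair cells, so it cannot show whether RNA of these alone was lost. The filter was applied to IPs and inputs separately, so both medians may rest on different members. That holds only as far as the log2(TPM + 1) scale, which understates changes of low genes, can show a loss. Without Prestin control IP replicate 1 the hair bundle median in the IP at 24 h was -0.34, and without any other single library it was -0.56 to -0.71. The fall thus rests more on that library than on any other. The test cannot tell whether the rest is a response to noise.

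Counts were compared with those from other divisions of the same libraries. In each case 1 division, the real one, gave as many genes. For enrichment the real counts were 13218 and 10746, and the highest of the others, out of 100 divisions, were 8003 and 4100. Of the others drawn for the outer hair cell IP, 7 parted every one of the 9 homogenates as the real one does, with 8003 as the highest, and those that parted fewer reached 4596. For the supporting cell IP, 11 parted all 7, with 3893 as the highest, and those that parted fewer reached 4100. In the inputs, 1213 genes at 6 h stood against at most 2 (60 divisions), 631 at 24 h against 69 (100) and 2284 between both times against 751 (100). The difference of enrichments gave 4249 against 650 (100). With 3 libraries per group there are only 10 divisions, too few for a share under 0.05: the outer hair cell IP had 940 against 15 at 6 h, 1041 against 5 at 24 h and 17 against 4 between both times. The Prestin inputs had 661 against 3 and 733 against 3, and the outer hair cell IP less its input had 420 against 10 and 181 against 5.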

How the results depend on the processing

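The alternatives with a mean of at least 5 TPM and without mitochondrial genes, Malat1 and Mir6236 were chosen after seeing the data, and so were the tests that use them. A count was taken as the same within 1.5 times, and else as moved. A gene's value was taken as the same where its sign and call were kept, whatever its size. It was weaker where it lost a call, stronger where it gained a call and reversed where its sign changed. Over all results and alternatives, 4315 values were the same by these rules, 650 weaker, 20 stronger, 174 moved and 5 reversed. Of the named genes, every alternative kept the call of 30 of 36 in the outer hair cell enrichment, 26 of 34 in the supporting cell enrichment, 41 of 48 in the inputs at 6 h and 31 of 33 at 24 h, 11 of 29 and 9 of 27 in the outer hair cell IP at 6 h and 24 h, and 0 of 21 and 0 of 7 in the supporting cell IP. It kept 0 of 6 and 0 of 7 in the outer hair cell IP less its input, 0 of 5 in the supporting cell IP less its input at 6 h, 2 of 7 and 0 of 5 in the difference of the pull-downs and 1 of 7 in that of the inputs at 6 h. Between both times it kept 0 of 3 and 0 of 4 in the outer hair cell and supporting cell IPs and 6 of 6 in the inputs, and 16 of 16 in the difference of enrichments. Where a cause is not named, the cause was not tested. Depth is unknown, so what it limits was not tested.

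With median-of-ratios scaling, Sox2 (-0.54) and Otof (-0.05) reversed in the outer hair cell enrichment and Rpl22 (-0.72) in the supporting cell enrichment, where Rpl22 also reversed without mitochondrial genes, Malat1 and Mir6236 (-0.12) and in control libraries only (-0.17). That scaling gave 6900 genes for the supporting cell enrichment, 307 and 573 for the outer hair cell IP at 6 h and 24 h, 47 and 24 for it less its input, and 148 for it less the supporting cell IP at 6 h. The number of lists past the threshold became 5 for the supporting cell IP less its input at 6 h, 7 for the supporting cell IP at 24 h and 1 for the difference of the inputs at 6 h. Control libraries only gave 4655 genes for the supporting cell enrichment.

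A pseudocount of 0.1 gave 35 and 26 genes for the outer hair cell IP less its input at 6 h and 24 h, 242 for the supporting cell IP at 6 h, 5 for it less its input at 24 h, and 277 and 3 for the difference of the inputs. No filter gave 415 for the outer hair cell IP at 6 h, 66 for the supporting cell IP at 6 h, 79 and 33 for it less its input, 49 for the pull-downs at 24 h and 6 for the inputs at 24 h. A mean of at least 5 TPM, which tests fewer genes, gave 163 and 17 for the outer hair cell IP less its input, 33 and 0 for the supporting cell IP less its input, 11 for the supporting cell IP at 24 h, 55 and 11 for the difference of the pull-downs and 0 for the inputs at 24 h. Without mitochondrial genes, Malat1 and Mir6236 the outer hair cell IP less its input gave 276 and 73.

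With the homogenate as a block, which pairs IP and input, the outer hair cell IP less its input gave 28 and 20 genes and the supporting cell IP less its input 3 and 2. With the replicate number as a block, though these libraries share only a number, the outer hair cell IP gave 91 and 106, the inputs 643 and 329, the difference of the pull-downs 35 and 9 and that of the inputs 104 and 0. One fit over IP and input libraries gave 4256 and 4295 for the outer hair cell IP and 1734 and 566 for the supporting cell IP.

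Leaving out each library or homogenate in turn gave 12673 to 12988 genes for the outer hair cell enrichment, 9781 to 10986 for the supporting cell enrichment and 3350 to 5055 for their difference. It gave 81 to 798 and 70 to 978 for the outer hair cell IP at 6 h and 24 h, 4 to 75 and 0 to 30 for the supporting cell IP, and 783 to 1619 and 443 to 664 for the inputs. It gave 32 to 819 and 15 to 413 for the outer hair cell IP less its input, 4 to 454 and 8 to 34 for the supporting cell IP less its input, 53 to 306 and 20 to 220 for the difference of the pull-downs, and 73 to 2103 and 0 to 39 for that of the inputs.

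With an estimated correlation, the call held for 7 of 14 lists in the inputs at 6 h, 8 of 16 at 24 h and 6 of 10 between both times, 3 of 16 in the supporting cell enrichment, 4 of 11 in the difference of enrichments, 1 of 16 and 1 of 15 in the Prestin inputs, and 4 of 15 in the Sox2 inputs at 24 h. It held for none in the other comparisons. With an estimated correlation, camera also takes the residual degrees of freedom of the fit. In the noise comparisons these were 6 in the outer hair cell IP, 4 in the supporting cell IP and 12 in the inputs of both strains. Calls lost in the IPs can thus reflect small fits as well as correlation between genes. With the homogenate as a block, chemokines in the outer hair cell enrichment (adjusted p = 0.0719) and stria markers in the supporting cell IP less its input at 24 h (0.0716) lost their calls. The number of lists called for the outer hair cell IP less its input at 6 h went from 2 to 5.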

Other observations

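The tests of this part were chosen before the results were seen, except those on genes listed at 0. Of 14 clock genes in the inputs at 6 h, 2 rose and 2 fell (4 and 3 adjusted over the list alone), and the list did not pass (median -0.02, adjusted p = 0.677). Nfil3 rose by 1.26 ± 0.22 (adjusted p = 0.00238) and Bhlhe41 fell by 0.62 on the log2 scale (adjusted p = 0.000551). As a list, clock genes were among the enriched genes of both pull-downs: 15 of 16 were higher in the outer hair cell IP (15 adjusted over the list alone, median 1.53, 0.71 above the median gene, adjusted p = 0.00065, adjusted p = 0.309 with an estimated correlation). In the supporting cell IP 16 of 16 were (16 adjusted over the list alone, median 1.24, 0.59 above the median gene, adjusted p = 0.00026, adjusted p = 0.127 with an estimated correlation).

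Every library listed both Xist (6.93 to 292 TPM), which is expressed from the inactive X of females, and the Y-linked Ddx3y (6.38 to 79.9 TPM). Bpifa1, a secreted protein of airway epithelium, stood at 12740 and 4029 TPM in the Sox2 24 h IP replicates 3 and 1 and at 401 TPM in replicate 2. Mir6236 was listed at 3452 to 17940 TPM in the Sox2 libraries and at 0 to 30.9 TPM in the Prestin libraries. Of the genes listed for both strains, 194 with a mean of at least 5 TPM in the Prestin libraries were at 0 in all Sox2 libraries, and 69 the reverse. Fzd6 was 1 such gene, with a mean of 10.2 TPM in the Prestin inputs.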
